A study of Homo sapiens with 10 samples.

How the data were processed

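The series measured total RNA from SH-SY5Y cells, an established line derived from a human neuroblastoma and widely used as a model of catecholaminergic neurons. There were 10 arrays, 5 from untreated cells and 5 from cells treated with paraquat, a herbicide that cycles between redox states in cells and gives rise to superoxide. Per the labels' protocols, RNA was extracted with a phenol reagent and cleaned on silica columns, ribosomal RNA was depleted, and biotin-labelled material was hybridised to Affymetrix GeneChip Exon 1.0 ST arrays. The dose and duration of the treatment are not given in the sources used here.

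The deposited table holds log2 expression values that the authors produced with RMA, per the submitters' processing notes. RMA subtracts a background estimate, equalises the distributions of the arrays and summarises the probes of each feature. The software, its version, the level of summarisation, any filter and the genome build are not given in the sources used here. That the scale is log2 was read from the range of the values, with a minimum of 1.07 and a maximum of 14.37 over the arrays. The table has 1 value per transcript cluster, a set of exon probes assigned to a locus, so that altered use of single exons cannot be separated from altered expression of the whole gene. No detection calls or probe-level values were used here, and a dim row cannot be told from background. RMA pulls weak signals together, which shrinks fold changes of dim transcripts. The array carries probes that can bind more than 1 member of families with nearly identical sequence, such as the histones and metallothioneins, so values of single members of those families are uncertain.

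The table of the platform's annotation, whose age is not given in the sources used here, assigned 1 gene symbol to 14432 of the 22011 rows, several to 2408 and none to 5171. Of the rows with 1 symbol, 14404 matched a gene of the RefSeq table of assembly GRCh38.p14 through their gene identifier. The symbols were taken from that table, and 0 of them differed from the annotation. The assembly of the annotation is not named, so no coordinates are printed and the RefSeq table served only for names. Rows with several symbols were tested and counted among the rows but did not stand for a gene or enter a list. A few with large changes are named with all their symbols. For statements on genes, the row with 1 symbol and the highest mean over all arrays stood for the gene, which gave 14232 genes. Of 197 genes with several such rows, 3 (CSNK1G1, SNU13 and TOR1AIP2) had rows that changed in both directions.

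Paraquat was compared with control on the deposited values, with no further scaling and no filter, by a linear model per row with empirical Bayes moderation in limma 3.58.1 under R 4.3.3. The model had the group as its only term and 8 residual degrees of freedom, to which moderation added 3.06. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all 22011 rows, and a row was called changed at an adjusted p under 0.05. Every adjusted p of a gene comes from this limma model. Errors of log2 changes are moderated standard errors, and errors of group means are standard deviations over 5 arrays. The labels do not say whether the arrays of a group came from separate cultures, so the p-values measure the spread between these arrays, which may be technical only. The number of arrays limits the precision: the median standard error of a log2 change was 0.13.

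The gene lists, 36 in number, were fixed before the data were examined, as were the tests, the rule for naming genes and all alternatives except those said to have been added later. Older symbols in the lists were matched through the synonyms of the RefSeq table. Each list with at least 3 measured members was tested with limma's camera at a preset correlation of 0.01 between genes, two-sided, with adjustment over the 34 lists tested. Camera asks whether the genes of a list shifted relative to the other genes. The test was repeated with a correlation estimated for each list and with fry, which asks whether a list's genes moved on balance in 1 direction. Confidence intervals of 95% for list medians came from 10000 bootstrap draws of the members. Percentiles of list medians refer to 10000 random lists matched on mean expression in 20 bins. Members were counted at the threshold over all rows and also with p-values adjusted over the list alone. The lists shared 6 of their 783 measured genes.

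The text names the 12 genes with the largest increases and the 12 with the largest decreases among those that passed the test and whose arrays did not overlap between the groups. Within each list it names up to 4 passing members with the largest absolute changes, or up to 2 members as values where none passed. Members that moved against the rest of their list, a few abundant members, the rows with several symbols, and the genes of the closing observations were added after their values were seen.

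Arrays were compared by Pearson correlation and principal components of the row-centred values, with an exact permutation test of a component's scores over the 252 ways to choose 5 of 10 arrays. No 2 arrays held identical values, and the smallest root mean square difference within a group was 0.31 on the log2 scale. On simulated arrays with the rows' own means and residual spreads, 200 of 22011 rows were changed by known amounts. The model recovered 38% of the rows changed by 0.5 on the log2 scale, 78% at 1, 96% at 2 and 100% at 3, and called 11 unchanged rows among 167 calls. Camera called the 1 list that had been shifted by 0.5 and no other. The simulated rows varied independently, so this does not test camera on correlated genes, and estimated correlations within lists reached 0.565 in the data. Because 4397 rows changed in the data, the recovery rates need not carry over.

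The alternatives were quantile normalization and median centring of the arrays, leaving out the 33.3% of rows with the lowest means, an intensity trend with robust moderation, array weights, consecutive sample numbers as a block, each array left out in turn, a test against a minimum fold of 1.2, an adjusted p under 0.01, no moderation, 1 row per gene, the mean of all rows of a gene, and the estimated correlation and fry named above. Leaving out control 11 and paraquat 12 together was added after their position among the arrays had been seen. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.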

Results

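Expression was measured in SH-SY5Y neuroblastoma cells on 10 exon arrays, 5 from untreated cells (controls 7, 11, 13, 17 and 19, numbered as in the sample titles) and 5 from paraquat-treated cells (paraquat 8, 12, 14, 18 and 20). Array medians lay between 6.78 and 6.93 on the log2 scale. The comparison asks which transcripts differed between treated and untreated cells.

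The first principal component held 42.1% of the variance and separated the groups, with all control scores between -34.4 and -31.5 and all paraquat scores between 24.9 and 39.3 (exact two-sided permutation p = 0.00794, the smallest that 5 against 5 arrays can give). Correlations across rows lay between 0.977 and 0.993 within groups and between 0.962 and 0.982 across groups. The second component, with 18.2% of the variance, set control 11 (score -49.0) and paraquat 12 (-27.9) apart from the other arrays. Control 11 also had the widest residuals, with an SD of 0.358 on the log2 scale against 0.215 to 0.274 for the other controls.

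**Figure D1:**
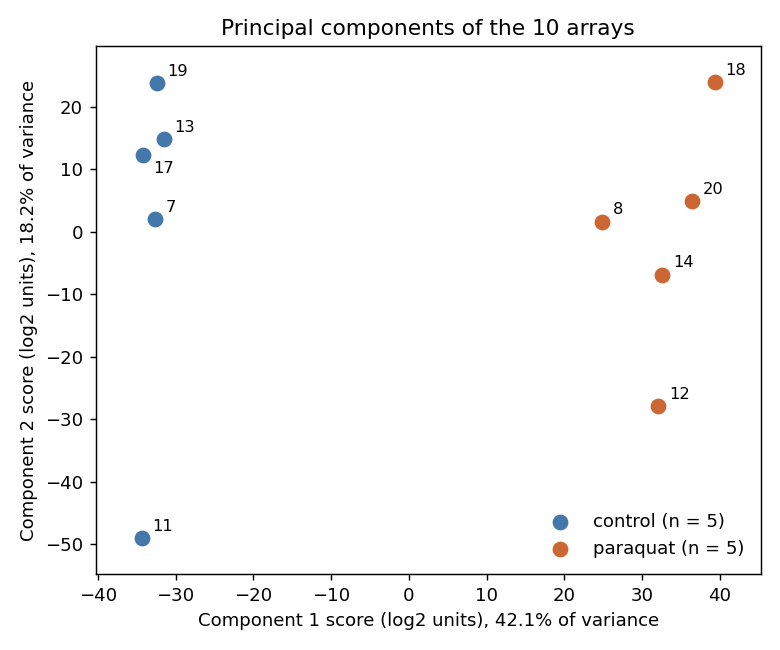
Scores of the 10 arrays on the first and second principal components of the row-centred log2 values, with points coloured by group and numbered as the samples. The groups lie on opposite sides along the first component (42.1% of the variance), and control 11 and paraquat 12 have scores of -49.0 and -27.9 on the second.

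After paraquat, transcripts of stress signalling and inflammation rose, and transcripts of cell division and sympathetic neuron identity fell. Replication-dependent histone genes also fell as a list at the preset correlation, but that call did not hold with an estimated correlation (adjusted p = 0.159). CXCL8, the neutrophil-attracting chemokine interleukin-8 (transcript cluster 2731332), rose 26.9-fold, from 6.70 ± 0.96 to 11.45 ± 0.37 (log2, mean ± SD, n = 5 arrays each). Its value in control 11 was 8.32, against 5.96 to 6.78 in the other controls. SLC7A11, the cystine importer of the plasma membrane (transcript cluster 2786322), rose 25.3-fold, from 6.09 ± 0.16 to 10.75 ± 0.21. TXNIP, which binds thioredoxin (transcript cluster 2356115), fell 11.3-fold, from 10.77 ± 0.14 to 7.27 ± 0.24, and LMO3, a transcription cofactor with a role in neuroblastoma (transcript cluster 3446137), fell from 7.33 ± 0.12 to 3.86 ± 0.19. That paraquat mean lies within the dimmest of 5 equal groups of rows (means up to 4.18), so the size of the fall is uncertain. The same holds for the paraquat means of KIT (4.05) and IFIT1 (3.93), the control mean of ULBP1 (3.35) and both means of FABP7 (3.56 and 3.02). Of 22011 rows, 4397 changed (20.0%), 1873 upward and 2524 downward, with 387 raised and 403 lowered at least 2-fold. After median centring of the arrays 2241 rose and 2211 fell, so the excess of lowered rows depends on the scaling. Counted by gene, 1359 of 14232 rose and 2025 fell. The arrays of the groups did not overlap in 16.2% of rows, where chance gives 0.794%. The number of changed rows was 1648 when tested against a minimum fold of 1.2 and 2492 at an adjusted p under 0.01.

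Among the largest increases were secreted factors. Besides CXCL8, the chemokine CCL20 rose by 3.85 ± 0.28 (log2 change ± SE), the interleukin-6 family cytokine LIF by 3.48 ± 0.10 and the collagenase MMP1 by 3.48 ± 0.23. ULBP1, a ligand of the natural killer cell receptor NKG2D, rose by 4.25 ± 0.42 from a control mean of 3.35. The transcription factors BHLHE40, EGR1 and FOS rose by 4.16, 4.12 and 3.64, and DDIT3, a stress-induced transcription factor also known as CHOP, by 3.46. TRAF1, an adaptor of tumour necrosis factor receptors, rose by 3.76 ± 0.12 and IER3, an early response gene, by 3.55 ± 0.12. The largest decreases included the receptor tyrosine kinase KIT (-2.86 ± 0.19), the kinase MAP2K6 (-3.08 ± 0.16), the cholecystokinin receptor CCKAR (-2.64 ± 0.18), the proneural transcription factor NEUROG2 (-2.63 ± 0.23) and the membrane protein TMEM100 (-2.49 ± 0.26). They also held the histones H2BC3 (-3.12 ± 0.51), H3C12 (-2.70 ± 0.17), H1-5 (-2.46 ± 0.22) and H2AC12 (-2.42 ± 0.23), and HMMR, a mitotic spindle protein (-2.80 ± 0.19).

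**Figure D2:**
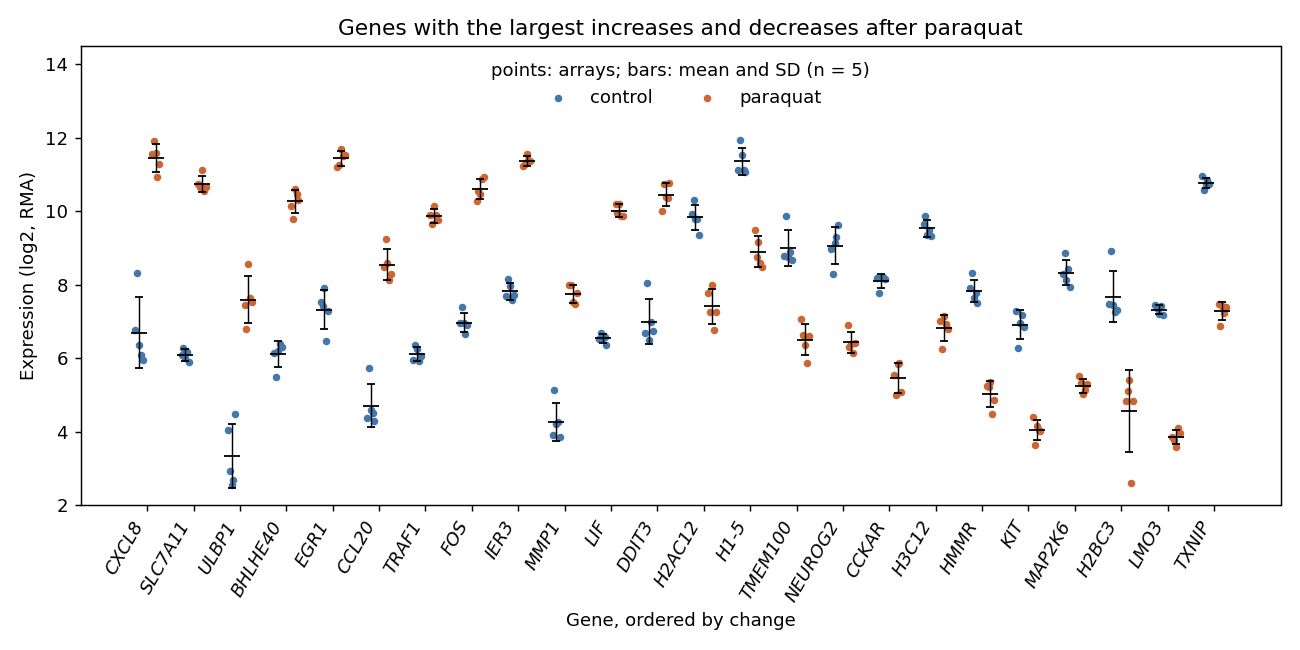
Log2 expression of the 12 genes with the largest increases and the 12 with the largest decreases, with 1 point per array and bars for the mean and SD of 5 arrays per group. In every gene shown the groups do not overlap, and changes run from 4.75 for CXCL8 to -3.49 for TXNIP.

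Genes of the NRF2 antioxidant response, which supply glutathione and reduce oxidised proteins, rose together. Of 19 measured members, 13 rose and 1 fell (14 and 1 adjusted over the list alone), with a median log2 change of 0.82 (camera adjusted p = 5.52e-12, and adjusted p = 0.0207 with an estimated correlation). After SLC7A11 the largest increases were in FTL, the ferritin light chain (2.80), SRXN1, which restores oxidised peroxiredoxins (2.45), and HMOX1, haem oxygenase 1 (2.45). The member that fell was the efflux transporter ABCC4 (-0.88). The list of superoxide and peroxide scavenging enzymes also holds thioredoxin, glutaredoxin and methionine sulfoxide reductase genes. In it, 0 of 18 passed upward and 4 passed downward (0 and 4 adjusted over the list alone, 2 to 4 lowered with 1 array left out), namely the methionine sulfoxide reductase MSRB2 (-1.14), CAT, which is catalase (-0.98), the glutaredoxin GLRX (-0.90) and the peroxiredoxin PRDX4 (-0.84). That list did not pass camera (median -0.05, adjusted p = 0.244), and SOD1, the cytosolic superoxide dismutase, had a change of -0.48 (adjusted p = 0.241). SOD2, the mitochondrial superoxide dismutase, and PRDX5 were in the list but had no row with 1 symbol, so their changes are not known here. Of 14 genes of iron handling, 4 rose and 0 fell (4 and 0 adjusted over the list alone): FTL, the mitochondrial importer SLC25A37 (1.02), SLC39A14 (0.84) and the transferrin receptor TFRC (0.62). The list's camera adjusted p was 0.0719 at a median of 0.08, and 0.035 after quantile normalization. The FTL row had a control mean of 6.53, below the array median although ferritin is abundant in most cells, and whether this row measures FTL or a related sequence was not tested. Of 4 metallothioneins, MT3 rose (0.39) and none fell (1 and 0 adjusted over the list alone, 0 to 2 raised with 1 array left out), with a list median of 0.23 (adjusted p = 0.191).

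The ATF4 integrated stress response, which covers amino acid synthesis and transport and the loading of transfer RNAs, was the list with the smallest camera p. Of 35 members, 30 rose and 0 fell (33 and 0 adjusted over the list alone), with a median of 1.08 (adjusted p = 2.92e-27, and adjusted p = 0.00278 with an estimated correlation). ATF3 rose by 3.46, the glutathione-degrading CHAC1 by 2.91 and PPP1R15A, a regulatory subunit of the phosphatase for initiation factor eIF2 alpha, by 2.66. GDF15, also in the fixed list, was not among the measured members. A row assigned to both GDF15 and MIR3189 rose by 5.54 (adjusted p = 1.25e-08). Chaperones of the endoplasmic reticulum did not follow as a list (median 0.05, adjusted p = 0.129), although the list passed upward after quantile normalization (median 0.11, adjusted p = 0.0452): 5 of 20 rose and 1 fell (5 and 2 adjusted over the list alone, 0 to 3 lowered with 1 array left out). Those that rose most were HERPUD1 (1.21) and EDEM1 (1.15), both of the degradation of misfolded proteins, the stress sensor ERN1 (1.10) and DNAJB9 (0.85), whereas the main lumenal chaperone HSPA5 had a change of 0.04 (adjusted p = 0.894). The heat shock list split, with 2 of 13 members raised and 3 lowered (3 and 5 adjusted over the list alone, 1 to 3 and 3 to 5 with 1 array left out). DNAJB4 (1.36) and DNAJB1 (0.40) rose, while HSPB1 (-0.80) and HSPH1 (-0.42) fell. Its median was -0.03 and its mean 0.05, and camera gave no shift (adjusted p = 0.93). HSPA1A and HSPA1B, also in that list, had no row with 1 symbol and were not among the measured members.

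Targets of p53 rose: 22 of 24 passed upward and 0 downward (22 and 0 adjusted over the list alone), with a median of 1.29 (adjusted p = 1.13e-22, and adjusted p = 0.0178 with an estimated correlation). The death receptor FAS rose by 2.81, GADD45A by 2.67, the cyclin-dependent kinase inhibitor CDKN1A by 2.47 and PLK2 by 2.45. Among 20 members of the BCL2 family and caspases, 6 rose and 2 fell (7 and 2 adjusted over the list alone, 1 to 2 lowered with 1 array left out), at a median of 0.18 (adjusted p = 0.0729, and 0.0399 after quantile normalization). The proapoptotic PMAIP1 (1.59), BBC3 (0.78) and BAK1 (0.68) were among those that rose, and CASP6 (-0.73) fell. The first 2 of these are also p53 targets in the other list.

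Immediate early genes, which respond within minutes to many stimuli, had the highest median of all lists, 1.57. Of 20 members 18 rose (camera adjusted p = 4.17e-22, and adjusted p = 0.00601 with an estimated correlation), led by EGR1, FOS, IER3 and the nuclear receptor NR4A1 (2.60), and MYC fell (-0.47), with the counts of 18 and 1 unaltered adjusted over the list alone. Genes of NF-kB and inflammatory signalling rose in 12 of 16 cases and fell in 0 (13 and 0 adjusted over the list alone), at a median of 1.34 (adjusted p = 8.03e-15, and adjusted p = 0.0144 with an estimated correlation). Besides CXCL8 and LIF, the prostaglandin synthase PTGS2 rose by 2.98 and IL1B by 2.80, while IL6 and TNF had changes of 0.21 and 0.14 that did not pass. Interferon-responsive genes did not shift as a list: 2 of 16 rose and 4 fell (2 and 4 adjusted over the list alone, 2 to 3 lowered with 1 array left out), with a median of 0.03, a mean of -0.05 and an adjusted p of 0.997. The transcription factors IRF1 (1.39) and IRF7 (0.34) rose, and the antiviral effectors IFIT1 (-1.50) and OAS1 (-0.58) fell. Beside the inflammatory genes, 2 of 9 leukocyte markers rose and 0 fell (2 and 0 adjusted over the list alone), CD68 by 1.33 and CD14 by 0.64, whereas the pan-leukocyte marker PTPRC had a change of 0.06 (adjusted p = 0.71). The leukocyte list's median was 0.06 (camera adjusted p = 0.129), and without the dimmest 33.3% of rows it was 0.64 and passed (adjusted p = 0.0271).

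**Figure D3:**
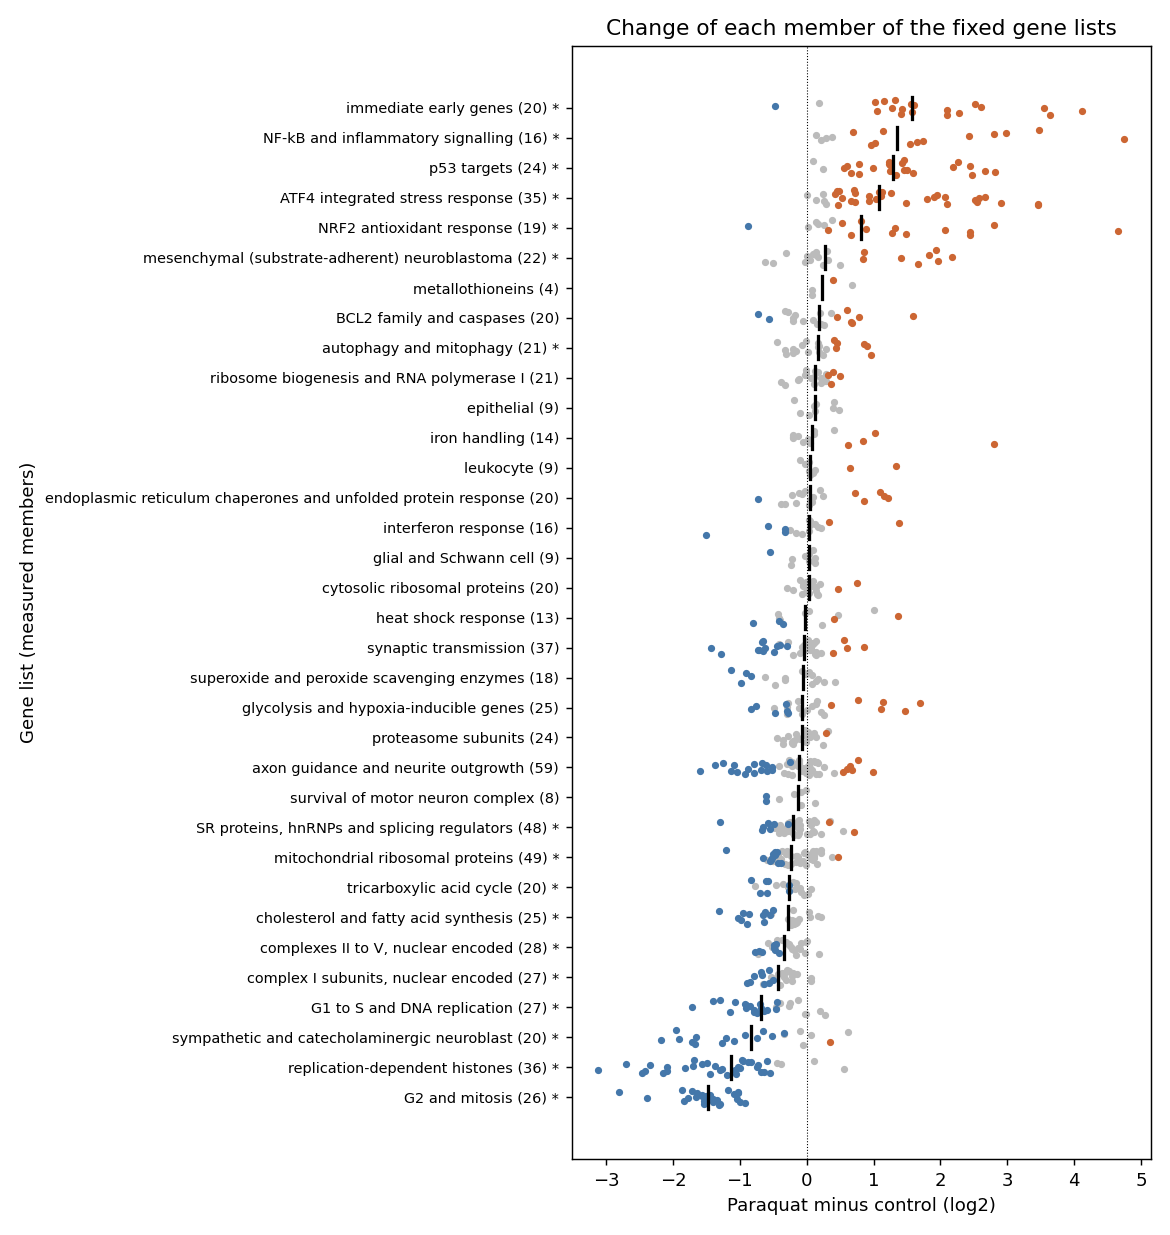
Log2 change (paraquat minus control) of each measured member of the 34 tested lists, 1 point per gene, orange where it rose, blue where it fell and grey where it did not pass; black bars mark list medians, the number of measured members stands in parentheses, and an asterisk marks an adjusted camera p under 0.05. Medians run from -1.48 for G2 and mitosis to 1.57 for immediate early genes.

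Genes of cell division fell. All 26 measured genes of G2 and mitosis passed downward (26 adjusted over the list alone), with a median of -1.48 (camera adjusted p = 7.39e-22, and adjusted p = 0.0426 with an estimated correlation). Besides HMMR, the proliferation marker MKI67 fell by 2.38, DLGAP5 by 1.87 and the mitotic kinase AURKA by 1.84. A row assigned to both KIF20A, a gene of the fixed list, and CDC23 fell by 2.54 and was not counted in the list. Of 27 genes of G1 to S and DNA replication, 18 fell and 0 rose (19 and 1 adjusted over the list alone), at a median of -0.68 (adjusted p = 2.35e-08, and adjusted p = 0.223 with an estimated correlation). The ribonucleotide reductase subunit RRM2 (-1.72), UHRF1 (-1.40), GMNN (-1.30) and the cyclin CCNE2 (-1.15) fell most, while the cyclin CCND1 had a change of 0.28 that did not pass. Replication-dependent histone genes fell in 32 of 36 cases and rose in 0 (34 and 0 adjusted over the list alone), with a median of -1.13 (adjusted p = 1.21e-17, and adjusted p = 0.159 with an estimated correlation). The values of single histone genes are uncertain because their sequences are nearly identical.

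Nuclear genes of the respiratory chain were lower after paraquat by smaller amounts. Of 27 subunits of complex I, 9 fell and 0 rose (10 and 0 adjusted over the list alone), at a median of -0.43 (camera adjusted p = 0.000115, and adjusted p = 0.432 with an estimated correlation). The largest decreases were in NDUFA6 (-0.89), NDUFA8 (-0.84), NDUFB7 (-0.79) and NDUFS6 (-0.68). Of 28 subunits of complexes II to V, 8 fell and 0 rose (11 and 0 adjusted over the list alone), at a median of -0.33 (adjusted p = 0.000538, and adjusted p = 0.432 with an estimated correlation). UQCR10 (-0.78), UQCR11 (-0.71) and UQCRQ (-0.67) of complex III and COX5B (-0.49) of complex IV fell. Of 49 mitochondrial ribosomal proteins, 11 fell, including MRPS34 (-1.21), MRPL35 (-0.66), MRPL18 (-0.56) and MRPL28 (-0.54), and MRPS2 rose (0.46), with 11 and 1 adjusted over the list alone and 5 to 11 lowered and 1 to 4 raised with 1 array left out. Their median was -0.23 (adjusted p = 0.0251, and adjusted p = 0.678 with an estimated correlation). Control 11 stood above the other controls in these lists, with a complex I mean of 9.28 against 8.58 to 8.76. Without control 11 the medians were -0.29 for complex I, -0.23 for complexes II to V and -0.09 for the mitochondrial ribosomal proteins, and the last call ended (adjusted p = 0.288). The mitochondrial ribosomal call also ended without paraquat 18 (adjusted p = 0.0587), without both control 11 and paraquat 12 (adjusted p = 0.112), after quantile normalization (adjusted p = 0.0562), with array weights (adjusted p = 0.0552), without the dimmest rows (adjusted p = 0.11) and with fry (adjusted p = 0.122).

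In the tricarboxylic acid cycle list 7 of 20 genes fell and 0 rose (9 and 0 adjusted over the list alone, 4 to 7 lowered with 1 array left out), at a median of -0.27 (adjusted p = 0.00118, and adjusted p = 0.0769 with an estimated correlation). Those named by size are the pyruvate dehydrogenase kinases PDK3 (-0.83) and PDK1 (-0.61), which restrain entry of pyruvate into the cycle, and the isocitrate dehydrogenases IDH2 (-0.69) and IDH1 (-0.60). Genes of cholesterol and fatty acid synthesis fell in 11 of 25 cases and rose in 0 (12 and 0 adjusted over the list alone), at a median of -0.28 (adjusted p = 8.93e-05, and adjusted p = 0.0769 with an estimated correlation). ELOVL6 (-1.32) and SCD (-0.95), which elongate and desaturate fatty acids, and EBP (-1.02) and TM7SF2 (-0.98) of sterol synthesis fell most. Glycolytic and hypoxia-inducible genes split into 6 raised and 6 lowered of 25 (7 and 7 adjusted over the list alone, 3 to 7 lowered with 1 array left out), with a median of -0.07, a mean of 0.11 and no shift by camera (adjusted p = 0.678). ADM (1.69), PFKFB3 (1.47) and NDRG1 (1.14) rose, as did TPI1 (1.11), whose row had a control mean of 4.12, far under the array median for an abundant enzyme, so that this row may not measure TPI1. Lactate dehydrogenase LDHA fell (-0.75).

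Genes of sympathetic and catecholaminergic neuroblasts fell. Of 20 members 14 fell and 1 rose (14 and 2 adjusted over the list alone, 1 to 2 raised with 1 array left out), with a median of -0.84 (camera adjusted p = 4.82e-07, and adjusted p = 0.0104 with an estimated correlation). The transcription factors HAND1 (-2.18), TFAP2B (-1.96) and GATA2 (-1.91) and the noradrenaline transporter SLC6A2 (-1.72) had the largest decreases, and the vesicular monoamine transporter SLC18A2 rose (0.34). Tyrosine hydroxylase, TH, had a change of -0.06 (adjusted p = 0.685). Of 22 genes of mesenchymal, substrate-adherent neuroblastoma cells, 8 rose and 0 fell (9 and 3 adjusted over the list alone), at a median of 0.28 (adjusted p = 5.59e-05, and adjusted p = 0.03 with an estimated correlation), or 0.67 without the dimmest rows. FOSL2 (2.17), SNAI2 (1.97), TGFBI (1.93) and CCN1 (1.83) rose, while the collagens COL1A1 and COL3A1 had changes of -0.51 and -0.62 that did not pass. Glial markers did not shift, with 1 of 9 lowered (0 adjusted over the list alone, 0 to 2 with 1 array left out), FABP7 (-0.55), a median of 0.03, a mean of -0.07 and an adjusted p of 0.897. None of 9 epithelial markers passed (0 adjusted over the list alone), the largest values being 0.48 for KRT14 and 0.41 for CLDN4, at a list median of 0.12 (adjusted p = 0.244). CLDN4 passed under 6 alternatives, with adjusted p-values from 0.0071 to 0.0499, and KRT14 under 2, with 0.0362 and 0.0452.

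Axon guidance and synaptic genes changed in both directions. In axon guidance and neurite outgrowth 17 of 59 genes fell and 6 rose (18 and 7 adjusted over the list alone), with a median of -0.11 (camera adjusted p = 0.0729, and 0.0155 without control 11). The semaphorins SEMA6D (-1.60) and SEMA6A (-1.13), DPYSL5 (-1.37) and the adhesion molecule CNTN1 (-1.25) fell. Of 37 genes of synaptic transmission, 12 fell and 4 rose (12 and 4 adjusted over the list alone, 6 to 12 and 2 to 4 with 1 array left out), at a median of -0.04 (adjusted p = 0.335). DLG2 (-1.43), SYT4 (-1.28) and RAB3A (-0.73) fell and DLG4, the postsynaptic scaffold PSD-95, rose (0.86).

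Splicing regulators were slightly lower. Of 48 SR proteins, hnRNPs and other regulators, 7 fell and 2 rose (6 and 2 adjusted over the list alone, 1 to 4 raised with 1 array left out), at a median of -0.20 (adjusted p = 0.0311, and adjusted p = 0.411 with an estimated correlation). ELAVL2, a neuronal RNA-binding protein, fell by 1.30, HNRNPAB by 0.66 and HNRNPM by 0.65, and TRA2A rose by 0.70, whereas the mean of all its rows had a change of 0.27 that did not pass (adjusted p = 0.0579). That call ended without control 11 (adjusted p = 0.0667), without paraquat 8 (adjusted p = 0.0513) and without paraquat 18 (adjusted p = 0.0587), as well as after quantile normalization (adjusted p = 0.0839) and without the dimmest rows (adjusted p = 0.115). Of 8 genes of the survival of motor neuron complex, GEMIN6 (-0.61) and GEMIN4 (-0.61) fell and 0 rose (3 and 0 adjusted over the list alone, 1 to 2 lowered with 1 array left out), with a median of -0.13 (adjusted p = 0.205), or -0.05 without control 11 (adjusted p = 0.364).

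Of the lists of cytosolic ribosomal proteins, ribosome biogenesis, the proteasome and autophagy, only autophagy passed. Of the 60 cytosolic ribosomal proteins in the list, only 20 were measured by a row with 1 symbol. Among these 20, RPS21 (0.76) and RPL28 (0.47) rose and 0 fell (2 and 0 adjusted over the list alone, 1 to 2 raised with 1 array left out), at a median of 0.03 (camera adjusted p = 0.402). Without control 11 that median was 0.21 (adjusted p = 0.0667). In ribosome biogenesis, RRP12 (0.49), DDX21 (0.39), NOP2 (0.37) and UTP4 (0.31) rose and 0 of 21 fell (4 and 0 adjusted over the list alone, 2 to 5 raised with 1 array left out), at a median of 0.13 (adjusted p = 0.0729, 0.0408 without control 11 and 0.035 after quantile normalization). PSMD4 (0.29) was the 1 proteasome subunit of 24 that rose and 0 fell (0 and 0 adjusted over the list alone, 0 to 2 raised with 1 array left out), at a list median of -0.07 (adjusted p = 0.757), or 0.03 without control 11 (adjusted p = 0.414). Genes of autophagy and mitophagy rose in 6 of 21 cases and fell in 0 (6 and 0 adjusted over the list alone), at a median of 0.17 (adjusted p = 0.031, and adjusted p = 0.434 with an estimated correlation). They were led by MAP1LC3B (0.96), the transcription factor TFE3 (0.91), and the cargo receptors OPTN (0.85) and CALCOCO2 (0.46). A row assigned to both SQSTM1, a gene of the fixed list, and MRNIP rose by 2.01 (adjusted p = 1.98e-07). Having several symbols, that row was not counted in the list. The autophagy call ended without control 19 (adjusted p = 0.0601) and without paraquat 14 (adjusted p = 0.0595). It also ended with consecutive sample numbers as a block (adjusted p = 0.0656), which takes pairs that the labels do not name.

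**Figure D4:**
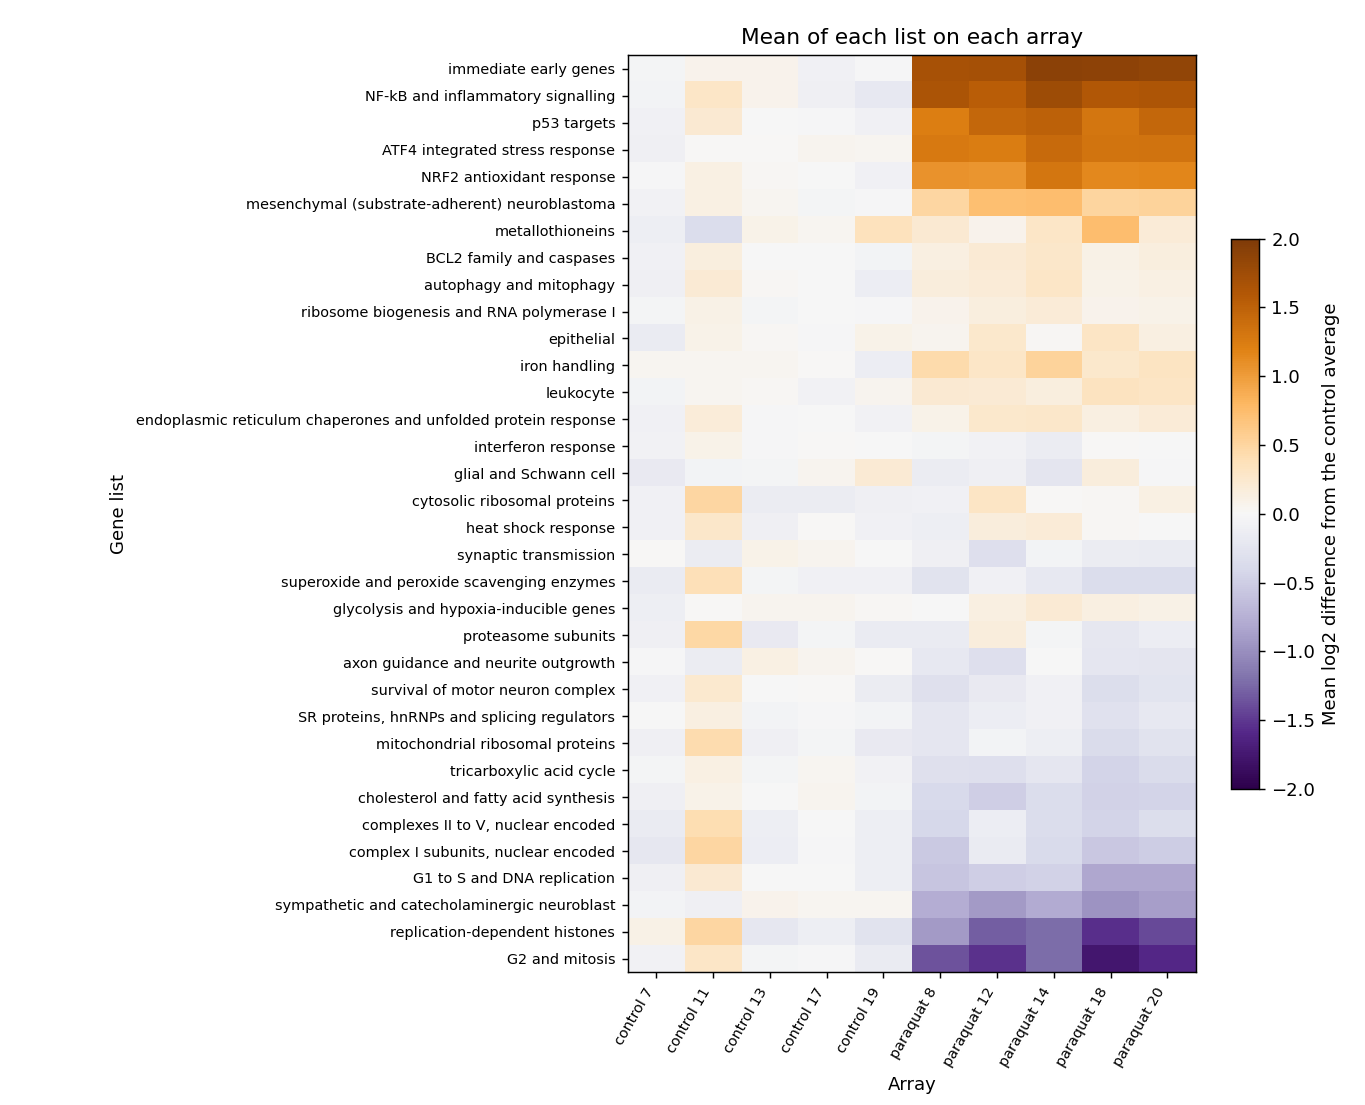
Mean of each tested list on each array as the log2 difference from the control average, from purple (-2) through white to orange (2), with lists ordered by the median change of their members. The 5 paraquat arrays carry the same colour in the lists at both ends, and control 11 is above the other controls in the complex I list, where its mean is 9.28.

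In all, 17 of 34 tested lists passed camera, 7 upward and 10 downward. With a correlation estimated for each list, 8 calls held: the NRF2, ATF4, p53, immediate early, NF-kB and mesenchymal lists upward and the G2 and mitosis and the sympathetic lists downward. The self-contained fry test passed 23 lists. The lists of mitochondrially encoded transcripts and small nucleolar RNAs had 0 members among rows with 1 symbol and were not tested. Of 23 counts of 0 after adjustment among list members, 7 had members at an unadjusted limma p under 0.05, with at most 3 in a list. With 1 array left out, 20 of the 45 counts of raised or lowered members above 0, in 17 lists, moved by over 1.5 times. The median did so, or changed sign, in 1 of the 17 lists that passed and in 14 of the 17 that did not. Of the 130 genes chosen by the naming rules 128 passed, and 110 of these passed with every array left out in turn. The 18 that did not, CASP6, DDX21, DNAJB1, FABP7, GEMIN6, GLRX, HNRNPM, MRPL18, MRPL28, MT3, NDUFA8, PDK1, PRDX4, PSMD4, RAB3A, RPS21, UQCR10 and UTP4, had adjusted p-values of at least 0.0192 with all arrays and of at most 0.106 with 1 array left out.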

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

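All tests on control 11 and paraquat 12 were chosen after the position of these arrays had been seen. The first test of shared handling and that of scaling were also written after their results, the second test of shared handling after the correlations of the pairs had been seen, and the slope test before its value was known. An array stood apart within its group, by a gap of more than 0.71 of the group's range, in 36 of 338 groups of 5 values examined, where chance gives about 1 in 20. Control 11 accounted for 15 of the 26 cases among named genes and for 9 of the 10 among list means.

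In control 11, transcripts of mitochondria, ribosomes and protein turnover were high. Its list means were 9.28 for complex I against at most 8.76 in the other controls, 9.46 for complexes II to V against at most 9.05, and 9.14 for mitochondrial ribosomal proteins against at most 8.67. They were 9.35 for cytosolic ribosomal proteins against at most 8.78, 10.26 for proteasome subunits against at most 9.74, and 9.05 for ribosome biogenesis against at most 8.94. The mean was 8.33 for superoxide and peroxide scavenging enzymes against at most 7.90, 8.19 for p53 targets against at most 7.95, and 9.56 for splicing regulators against at most 9.42. Among named genes past the gap of 0.71, control 11 was above the other controls in CCL20 (5.73), H2BC3 (8.91), TMEM100 (9.88), PRDX4 (9.40), GADD45A (9.19), NDUFA6 (9.70), NDUFS6 (9.99), CCNE2 (7.64), PMAIP1 (8.72), GEMIN6 (10.13) and IFIT1 (6.11). It was below them in CCKAR (7.79), TFAP2B (9.53), SEMA6A (6.41) and TRA2A (7.91).

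Control 11 and paraquat 12 lay together on the second principal component, and the deviations of their values from the group means correlated across rows at 0.461. The correlation was 0.464 after quantile normalization, so differences in distribution left between the arrays do not account for it. Array medians already lay between 6.78 and 6.93, so that normalization had little left to remove. It cannot decide whether other effects of scaling were involved. Shared handling of consecutively numbered samples stays open: of the 120 ways to match controls with paraquat arrays, 2, the consecutive one included, gave a mean correlation as high, but that mean contains the pair that prompted the test, and without it 2 of 24 did. Part of the paraquat response in control 11 stays open, with slopes of 0.0410 and 0.0523 of its deviation on the paraquat change, on either side of the bound of 0.05. The labels name no handling batch, so a shared batch could not be tested further.

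Other arrays stood apart in single genes or lists. Paraquat 18 was low for H2BC3 (2.60). Paraquat 8 was low for ATF3 (9.18) and TPI1 (4.58). Control 7 was low for CHAC1 (6.69), and paraquat 12 was low for CHAC1 (9.66) and HAND1 (6.64) and high for UQCR10 (9.29) and IDH2 (9.71). Paraquat 14 was high for SLC25A37 (9.53). Control 13 was high for SLC6A2 (9.79) and low for RPS21 (6.54), and control 19 was low for the mean of iron handling genes (8.04).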

How the results depend on the processing

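Leaving out control 11 and paraquat 12 together was chosen after seeing the data; all other alternatives were planned. No called list or gene reversed, and 0 of the 130 genes chosen by the naming rules had a sign change, while 21 medians of 7 lists that did not pass changed sign. The number of changed rows was 1648 (735 raised, 913 lowered) against a minimum fold of 1.2 and 2492 (1068 raised, 1424 lowered) at an adjusted p under 0.01, both stricter by construction. The other planned settings gave from 3570 with 1 row per gene to 6196 with array weights. With 1 array left out it ranged from 3396 without paraquat 20 to 4708 without control 11, with 1480 to 2066 raised and 1916 to 2642 lowered. Without both control 11 and paraquat 12 it was 4546, of which 3836 were among the 4397. Median centring gave 2241 raised and 2211 lowered, a raised share of 50.3% against 42.6%, so the excess of lowered rows did not hold. The first component held 40.9% to 46.8% of the variance with 1 array left out. Of the 34 lists, 8 passed with an estimated correlation. The estimates ran from 0.0144 for the sympathetic list to 0.565 for proteasome subunits, all above the preset 0.01. Whether that alone ended the other calls was not tested. With 1 array left out 16 to 18 passed. Over all alternatives the adjusted p ranged from 0.00611 to 0.678 for mitochondrial ribosomal proteins, which did not pass without control 11 (0.288) or paraquat 18 (0.0587), from 0.00902 to 0.411 for splicing regulators, which did not pass without control 11 (0.0667), paraquat 8 (0.0513) or paraquat 18 (0.0587), and from 0.00701 to 0.434 for autophagy, which did not pass without control 19 (0.0601) or paraquat 14 (0.0595). Single arrays left out also brought lists past the threshold: iron handling without control 7 (0.0394), paraquat 18 (0.0397) or paraquat 20 (0.0421), axon guidance without control 11 (0.0155) or paraquat 14 (0.0395) and ribosome biogenesis without control 11 (0.0408). Quantile normalization did so for chaperones of the endoplasmic reticulum (0.0452), iron handling (0.035), the BCL2 family (0.0399) and ribosome biogenesis (0.035). Among the 130 genes, calls ended in 103 combinations of a gene and an array left out, in 18 genes, and in 9 combinations of a gene and another setting, among them TRA2A with the mean of all its rows (0.27 against 0.70, adjusted p = 0.0579). KRT14 passed without paraquat 14 (0.0452) and with array weights (0.0362). CLDN4 passed without control 11 (0.0182), without both arrays (0.012), with array weights (0.0121), with the block (0.0071), after median centring (0.048) and with the mean of all its rows (0.0499).

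The main analysis was not paired, because the labels give the groups no shared replicate numbers and name no pairs. Taking consecutive numbers as pairs is a guess, fitted as an alternative only. That block gave 5379 changed rows against 4397 and 16 lists, ended 0 calls among the 130 genes, added CLDN4, and left autophagy without a call (0.0656). Deviations of consecutive arrays correlated at 0.226, 0.461, 0.0912, 0.172 and 0.121. The mean was -0.0515 for the other pairs of a control with a paraquat array. Deviations from a group mean cancel out within the group, so higher values in some pairs force lower ones in the others. That mean is therefore not an independent reference. Not every array correlated best with its neighbour. Fewer dim rows changed: in the dimmest of 5 equal groups by mean 96 rose and 61 fell, and in the next to brightest 502 rose and 779 fell. Whether weak signal over background accounts for this was not tested.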

Other observations

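The gene families, single genes and rows in the first paragraphs were chosen after their values were seen; the look at the brighter leukocyte markers alone was also chosen after, and the other tests of the inflammatory and the mitotic pattern and of other splits were written before. Genes were grouped by the letters of their symbols before the first digit, and the 177 groups with at least 10 measured genes were tested with camera. There were 4 that passed, and none did with an estimated correlation (adjusted p = 0.802 for each of the 4 with an estimated correlation). Receptors of the tumour necrosis factor family, TNFRSF, rose in 9 of 19 cases and fell in 0 (adjusted p = 0.00156), with TNFRSF12A up by 2.02, TNFRSF9 by 1.25 and the death receptors TNFRSF10B and TNFRSF10A by 1.25 and 1.23. Tetraspanins, TSPAN, fell in 12 of 21 cases and rose in 0 (adjusted p = 0.00205), led by TSPAN7 (-1.48) and TSPAN8 (-1.20). Dual-specificity phosphatases, DUSP, rose in 9 and fell in 3 of 22 cases (adjusted p = 0.0304), with DUSP5 up by 2.52, DUSP1 by 1.61, DUSP4 by 1.59 and DUSP6 by 1.56, of which DUSP1, DUSP5 and DUSP6 are also in the immediate early list. The co-chaperones DNAJB rose in 5 of 10 cases (adjusted p = 0.0186).

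CD274, which encodes PD-L1, rose by 2.68. PDCD1LG2, which encodes PD-L2, also rose, from a control mean of 3.86 among the dimmest rows, which leaves the size of the rise uncertain. MICB, a ligand of the same receptor as ULBP1, had a change of -0.07 (adjusted p = 0.747). The epidermal growth factor receptor ligand HBEGF rose by 2.93 and ERRFI1, an inhibitor of that receptor, by 3.12. The interleukin-6 family cytokine IL11 rose by 2.84, and SELE, an adhesion molecule of endothelium, by 3.25. KITLG, the ligand of KIT, rose by 1.33 while KIT fell by 2.86. The granule proteins VGF and SCG2 rose by 2.25 and 2.05, against a change of -1.66 in the granule protein CHGA. TXNIP fell by 3.49, and its paralogue ARRDC4, also regulated by glucose, had a change of -0.04 (adjusted p = 0.838). Rows without a symbol changed as well: row 3016148 rose by 4.68 and row 3429008 fell by 4.03, and 517 of 5171 such rows changed. The largest change of any row, 5.54, was in row 3824993, which is assigned to both GDF15 and MIR3189.

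Inflammatory genes rose, and the NF-kB median was 1.39 after quantile normalization. That normalization could alter it little, since array medians already lay between 6.78 and 6.93. This spread is far smaller than the NF-kB median of 1.34, which argues against differences in overall array level as the cause. By the marker values alone leukocytes in the cultures stay open, although the sample titles name only SH-SY5Y cells, an established line. The median of the leukocyte list was 0.0552 (95% interval -0.02 to 0.64) against a bound of 0.672, which is 0.5 of the median of the NF-kB list. The interval lay below the bound, which met the condition written before for a result against leukocytes. Most of the list's markers lie near the floor, where a row cannot be told from background, so meeting that condition does not decide the question. The 3 of 9 members above the dimmest 33.3% of rows had a median of 0.64 with an interval of 0.04 to 1.33 that includes the bound. With 3 genes drawn, this interval only spans their smallest and largest change and measures no spread between arrays, so it cannot decide the question. Without those dim rows the list passed camera (adjusted p = 0.0271, range over the alternatives 0.00194 to 0.361). PTPRC had a mean change of 0.06 (adjusted p = 0.71) at a control mean of 2.67. A larger share of substrate-adherent cells stays open too: the mesenchymal median was 0.277, with an interval of 0.09 to 0.86 that includes the bound, and it ranged from 0.191 to 0.668 over the alternatives.

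The fall of mitotic and histone genes is not a general fall of bright rows, since the median of the G2 and mitosis list lay at percentile 0 of 10000 lists matched on mean expression. A larger share of substrate-adherent and glial cells cannot be told apart by the lists used: the glial median was 0.0287, with an interval of -0.24 to 0.12.

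Of 100 splits of the 10 arrays into 5 and 5, 1, the real one, gave 4397 changed rows, against at most 1 in any other split. Every other split mixed the groups, so the group difference itself widened its residuals and kept its count low. The splits show that the changes follow the group labels. They cannot tell paraquat from anything else that the arrays of a group shared. The labels do not say whether these arrays came from separate cultures.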
